A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

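Per the labels, each array compared total RNA of 1 mutant culture, labelled with Cy5, with RNA of the NHP6A ∆nhp6B reference, labelled with Cy3, on Agilent yeast arrays. The deposited intensity values were read from the scanned images by Agilent Feature Extraction 10.5.1.1, per the file headers, and hold median spot and background signals for both channels. The deposited value table holds the log10 ratio of Cy5 over Cy3 that Feature Extraction computed, per the file headers, and it equalled that column of the array files spot by spot. Other deposited columns hold Feature Extraction's flags for outlier, saturated and well-above-background spots, per the file headers. The submitters' processing notes name limma, without a version and without saying for which step.

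The plan called for mean spot signals, which the files do not hold, so median signals were used. Of 45209 spots per array, 1417 controls were left out, and the other 43792 cover 6256 genes with 7 spots each. Spots that the scanner software had marked as outliers, 3.63% to 5.30% per array, were dropped. The plan left them out of the averages, and dropping them already before background correction, with spots whose local background was marked, was decided after a first fit had been seen. In that fit the deletion gave 41 calls. On the first deletion array the lowest net signal in the mutant channel was -665104, against -17 among unmarked spots, and the spread of the background model was 4214, against 1.63 without the marked spots. Agilent's processed signals and the deposited log ratios, which do not use this background model, gave 1337 and 1317. Background was corrected with limma's normexp (offset 50), the log2 ratios were normalized by loess within each array, and the spots of a gene were averaged. Genes were tested if they stood well above background in at least 1 channel on at least 2 arrays, which left 5839. Gene names came from a table of the R64 genome, which matched 5756 genes and left 500 under their systematic names, and which was used for names and neighbours only.

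A linear model with a mean per genotype was fitted with limma 3.58.1 in R 4.3.3 and moderated by eBayes (4 residual and 3.42 prior degrees of freedom). The 4 genotypes shared an estimate of each gene's spread. The p-values were adjusted by Benjamini and Hochberg's method over all genes of a comparison, and an adjusted p under 0.05 counted as a call. The lists of genes, 40 in all, and the comparisons were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over 160 tests. Where a channel was not well above background on either array, a fold change was given as a lower bound, per channel after loess and scaling between arrays. It sets the bright mean against, per array, the higher of the lowest signal among genes well above background and the dim gene's own signal. Where the dim gene's own signal was the higher on both arrays, as for TRP1 against the reference, the bound equals the fitted fold change. For a difference between genotypes this bound was held to the fitted fold difference at most, a step added after some bounds were seen to exceed it. For TRP1 and SMK1 the fold printed is therefore the fitted difference, and the bounds themselves were 16.8, 37.9 and 42.6 for TRP1 in P18A, F48A and M29A and 14.0 for SMK1 in F48A. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

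The genes named were chosen by a rule fixed beforehand. It took NHP6A and NHP6B first, then their nearest neighbours. It added the 10 largest increases and decreases of each genotype that passed with the same sign on both arrays, and the 5 largest each way of each difference between genotypes. From each list it took the 2 highest and 2 lowest members in the deletion, and all members of the lists of reported Nhp6 targets, HMG-box and FACT genes and selection markers. This gave 744 pairs of gene and comparison, of which 245 were called.

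The model fit and the tests, without the steps before them, were run on simulated log2 ratios with 200 changed genes among 5839, over 10 simulations. The ratios were drawn independently for each gene and array. They held no shared reference, dye effect, correlation between genes or spread that differs by genotype, so the rates need not hold for these data. Changes of log2 0.5, 1 and 2 were called in 37.9%, 83.1% and 97.4% of cases against the reference, and in 10.7%, 62.1% and 93.0% between genotypes. Of the calls, 4.92% were false, and a genotype with no change gave 0.1 calls on average. The median estimate was 0.999 of the true size. Over the 200 changed genes alone, a relative effect size set to 0.5 was read as 0.507. This does not check the relative effect sizes given below, which are over all genes tested or over the genes called.

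The alternatives tried were Agilent's processed signals, the deposited log ratios, no background correction, median centring without loess, scaling between arrays, the median of a gene's spots, no filter and a stricter filter on dim genes, the slide as a fixed or random block, a trended robust spread, only the arrays compared, stricter thresholds and leaving out each array. Keeping the outlier spots, and crossing the replicate numbers of F48A, were added after the data were seen. No probe sequences were used.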

Results

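Gene expression was measured in asynchronously growing budding yeast, Saccharomyces cerevisiae, on 8 two-colour Agilent arrays. Nhp6A and its paralogue Nhp6B are small, abundant HMG-box proteins that bind the minor groove of DNA and bend it, and every strain here lacked NHP6B. The reference strain kept wild-type NHP6A, and 4 other genotypes were compared with it, each on 2 arrays: a deletion of NHP6A, and strains whose NHP6A carried the P18A, F48A or M29A substitution. The series title names the question as how DNA bending by Nhp6A bears on transcription. Cy5 carried the mutant RNA and Cy3 the reference RNA on all 8 arrays, so a dye effect of a gene stays in its ratio to the reference and drops out of the differences between genotypes. The labels do not say how many cultures gave the reference RNA. The ratio was tested against 0, which leaves out the reference strain's own spread if 1 reference sample served all arrays.

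The median spot brightness over background lay between 321 and 1044.5 in the mutant channel and between 277.5 and 416.5 in the reference channel. Between 87.2% and 93.2% of spots stood well above background, and 0 spots were saturated. Across the 5839 genes tested, the log2 ratios of the replicate arrays correlated at 0.805 in the deletion, 0.640 in P18A, 0.511 in F48A and 0.373 in M29A. These are correlations across genes, which are not independent replicates. With 2 arrays per genotype and a spread shared by the genotypes, a typical gene's 95% interval reached 0.29 on the log2 scale either side of its mean against the reference. For a difference between genotypes it reached 0.40 either side. The labels call the replicates biological.

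NHP6A (YPR052C) was read first. In the deletion its Cy5 signal was not well above background on either array, and its level was at least 58.8-fold lower than in the reference (log2 ratio -6.36 ± 0.16, SE, n = 2, limma adjusted p = 3.02e-06). In P18A the NHP6A signal fell 4.55-fold (log2 -2.19 ± 0.16, limma adjusted p = 0.00187). Whether the transcript itself fell is left open, as weaker binding of the probe to it could not be told apart. In F48A and M29A the ratios were -0.30 ± 0.16 and -0.25 ± 0.16 and did not pass the test. NHP6B, which all strains lack by their labels, gave a signal well above background in both channels, and it read 0.55 ± 0.10 in the deletion (limma adjusted p = 0.0112) and between -0.14 and -0.01 in the substitution strains. Whether the NHP6B probe lies inside the deleted part is not given in the sources used here, so it does not check the labels. Of the genes beside NHP6A, the overlapping reading frame YPR053C was 2.23-fold higher in P18A, 1.60-fold in F48A and 2.09-fold in M29A, while MAK3 on the other side did not pass the test in any genotype. YBR089W, beside NHP6B, did not pass either, and YBR090C was too dim to be tested.

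**Figure D1:**
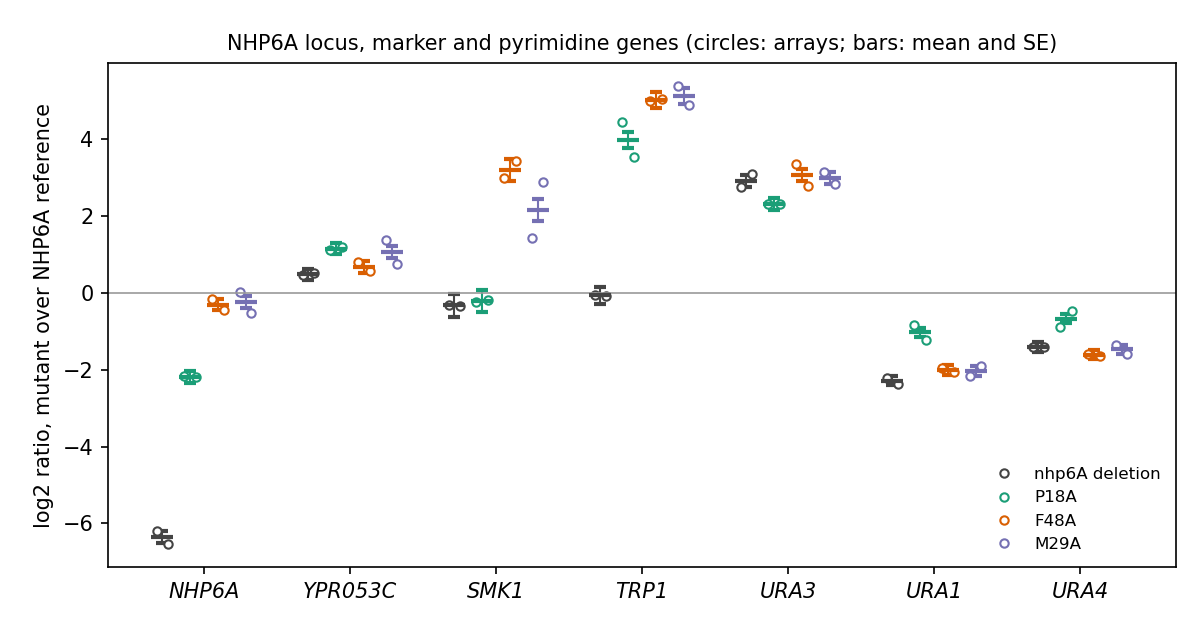
Log2 ratios of the mutant over the NHP6A reference for NHP6A, its neighbours YPR053C and SMK1, the marker genes TRP1 and URA3, and URA1 and URA4. Circles are single arrays and bars are the mean and SE of 2 arrays; NHP6A lies at -6.36 in the deletion and -2.19 in P18A, and TRP1 between 3.99 and 5.13 in the substitution strains.

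The nhp6A deletion changed 1434 of 5839 genes (24.6%), 838 higher and 596 lower, and 180 of them by at least 2-fold. Among the 10 largest increases were PIR3, a cell wall mannoprotein, which rose 9.39-fold (log2 3.23 ± 0.17, SE, n = 2, limma adjusted p = 0.000180), HSP12, a membrane heat shock protein, 7.15-fold (2.84 ± 0.21), GRE1, a stress-induced hydrophilin, 5.61-fold (2.49 ± 0.13), CTT1, the cytosolic catalase, 5.34-fold, NQM1, a transaldolase, 5.28-fold, HPF1, a cell wall mannoprotein, 5.18-fold, and HSP42, a small heat shock protein, 5.04-fold. URA3, which makes uridine monophosphate and serves as a selection marker, rose 7.56-fold, and the reading frames YBR116C and YLR112W rose 4.81-fold and 4.76-fold. The largest decreases after NHP6A were in the alpha-factor gene MF(ALPHA)2 (17.5-fold lower, log2 -4.13 ± 0.42), the low-affinity glucose transporter HXT1 (9.86-fold lower) and the phosphate transporter PHO84 (7.56-fold lower). MDH2, the cytosolic malate dehydrogenase, fell (log2 -2.57), as did NMD5, an importin (-2.47), and URA1, dihydroorotate dehydrogenase (-2.29). The alpha-agglutinin SAG1 (-2.24), the sodium-phosphate transporter PHO89 (-2.11) and the a-factor receptor STE3 (-2.09) fell too. Each of these genes moved the same way on both arrays, as the naming rule required.

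Of the 38 general stress genes measured, 20 rose and 0 fell in the deletion (25 rose adjusted over the list alone), and the list's median was 1.00 on the log2 scale. HSP12 and GRE1 led it, while YGP1 at -0.25 and GPD1 at -0.27 did not pass the test. limma's camera test called the list higher (adjusted p = 6.72e-09 with the preset correlation, adjusted p = 0.735 with an estimated correlation), and its median was 1.34 on slide 1 and 0.73 on slide 2. Of 21 heat shock chaperone genes, only SSA3, an Hsp70, rose (0.93 on the log2 scale), and limma's camera did not call that list (adjusted p = 0.801). Among 35 genes of the respiratory chain and ATP synthase, 17 rose and 0 fell (19 rose adjusted over the list alone), with a median of 0.51. CYC1, iso-1-cytochrome c, rose by 1.53 and QCR6, of the cytochrome bc1 complex, by 1.11, while ATP2 and ATP18 lay at -0.02 and -0.03 (camera adjusted p = 1.28e-06, adjusted p = 0.713 with an estimated correlation). On slides 1 and 2 the median was 0.49 and 0.57. Of 34 proteasome genes, 9 rose and 0 fell, both over all genes and adjusted over the list alone, led by PRE5 at 1.31 (median 0.23, camera adjusted p = 0.00156, adjusted p = 0.793 with an estimated correlation). The median was 0.35 on slide 1 and 0.18 on slide 2.

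Amino acid biosynthesis genes under Gcn4, the activator of starvation genes, also rose: 18 of 33 were higher and 0 lower (22 and 2 adjusted over the list alone), with a median of 0.39. SER3, of serine synthesis, rose by 1.70 and ARG4, of arginine synthesis, by 1.60, while ILV1 at -0.33 and LYS20 at -0.52 did not pass (camera adjusted p = 7.03e-07, adjusted p = 0.558 with an estimated correlation). Slide 1 gave a median of 0.48 and slide 2 one of 0.39. The 12 purine genes went both ways: GCV1 and GCV3, of the glycine cleavage system, rose by 2.08 and 1.55, and ADE17 fell (-1.09). Cell wall genes rose in 11 of 23 cases and fell in 2 (12 and 2 adjusted over the list alone; median 0.60, 0.37 on slide 1 and 0.70 on slide 2). SED1, a stress-induced mannoprotein, rose by 1.34, and CWP1, also a mannoprotein, fell (log2 -1.24) (camera adjusted p = 0.00154, adjusted p = 0.703 with an estimated correlation).

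The phosphate regulon fell: 11 of its 14 genes were lower and 0 higher (11 adjusted over the list alone), with a median of -0.73. PHO84 and PHO89 carried the largest decreases, and PHO8 at 0.08 and VTC1 at -0.01 did not pass (camera adjusted p = 1.24e-06, adjusted p = 0.368 with an estimated correlation). By slide, the medians were -0.82 and -0.72. Cytosolic ribosomal protein genes were lower in 42 of 138 cases and higher in 3 (49 and 4 adjusted over the list alone), with a median of -0.32. RPL8A (-1.84) and RPL18B (-1.62) fell the most, and RPS27A rose by 1.63 (camera adjusted p = 3.63e-09, adjusted p = 0.424 with an estimated correlation). On slides 1 and 2 the median was -0.37 and -0.23. Ribosome biogenesis genes fell in 6 of 54 cases and rose in 1 (0 and 0 adjusted over the list alone, by limma, where 15 were lower and 4 higher at an unadjusted p under 0.05). RRP5 fell (-0.63) and IMP4 rose by 0.67 (median -0.22, camera adjusted p = 0.0183, lost with median centring at adjusted p = 0.224, adjusted p = 0.867 with an estimated correlation). The median was -0.31 on slide 1 and -0.12 on slide 2. Of 12 hexose transporters, 3 fell, HXT1 and HXT4 the most (-3.30 and -1.79), and HXT5, which is used at low glucose, rose by 0.58. Glycolysis and fermentation genes fell in 6 of 16 cases, HXK2 (-0.92) and ADH1 (-0.84) the most (6 adjusted over the list alone; median -0.43, -0.42 on slide 1 and -0.39 on slide 2; camera adjusted p = 0.0494, adjusted p = 0.825 with an estimated correlation), and this camera call was lost with the slide as a block, from Agilent's processed signals, with no background correction and with the outlier spots left in the background fit.

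Among genes of cell type and cell cycle single members passed in both directions. Of 13 mating-type-specific genes, MF(ALPHA)2, SAG1 and STE3 fell, and STE6, the a-factor exporter, and STE18, a G protein subunit, each rose by 0.60. HO, the mating-type endonuclease, fell (-1.53), as did the cyclin genes CLN1 (-0.80), CLB6 (-0.66) and CLB1 (-0.65). Among the 12 G2/M genes 3 fell, and 3 fell adjusted over the list alone (median -0.29, camera adjusted p = 0.00441, adjusted p = 0.735 with an estimated correlation). On both slides the median was -0.30. Of 38 chromatin remodelling and histone chaperone genes 9 fell and 4 rose (13 and 5 adjusted over the list alone), VPS75 (-0.94) and CHD1 (-0.81) the most, with SPT4 at 0.64 (median -0.22, camera adjusted p = 0.0140, lost with median centring at adjusted p = 0.0859, adjusted p = 0.481 with an estimated correlation). Slide 1 gave a median of -0.13 and slide 2 one of -0.29. Of 10 histone genes 4 rose, HHT1 (0.90) and HHF1 (0.62) the most, and HTB2 fell (-0.48). Of the other HMG-box and FACT genes, the mitochondrial DNA packaging gene ABF2 rose by 0.45 and HMO1, a ribosomal gene factor, fell (-0.55), whereas ROX1, POB3, IXR1, NHP10 and SPT16 lay between -0.04 and 0.28 and did not pass.

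The 8 genes listed beforehand as reported Nhp6 targets were split. DDR2, a stress gene, rose by 1.82, CYC1 by 1.53 and the metallothionein copies CUP1-1 and CUP1-2, which share near-identical sequence, by 1.52 and 1.48, while HO fell (-1.53). GAL10 at 0.27, CHA1 at 0.20 and GAL1 at -0.13 did not pass (5 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 0.0579). Of the selection-marker genes, LYS2 rose by 0.66 and MET17 fell (-0.73), ADE2 and LEU2 did not pass, and TRP1 was not well above background in either channel. With the slide as a block 1348 genes passed in the deletion. The count was 266 without replicate 1 and 165 without replicate 2, 441 with median centring in place of loess, and 41 with the scanner's outlier spots left in the background fit, a choice changed after that count was seen. The deposited log ratios, made without that background fit, gave 1317.

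**Figure D2:**
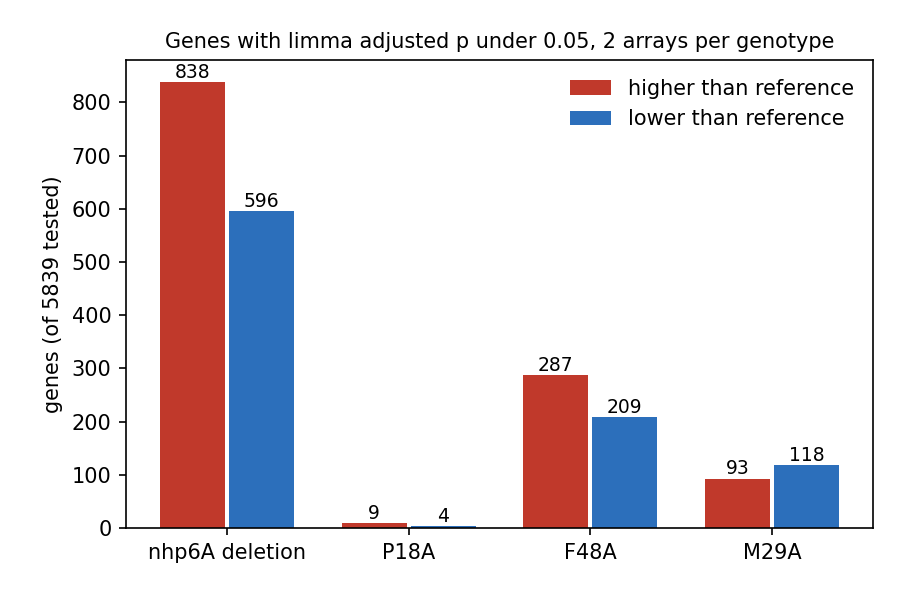
Number of genes higher (red) and lower (blue) than the NHP6A reference at a limma adjusted p under 0.05 in each genotype, out of 5839 tested on 2 arrays per genotype. The bars stand at 838 and 596 for the deletion, 9 and 4 for P18A, 287 and 209 for F48A, and 93 and 118 for M29A. The 4 genotypes shared an estimate of the spread in this fit. With only a genotype's own arrays in the fit, 1461 genes passed in the deletion, 339 in P18A, 3 in F48A and 0 in M29A. The order of the substitution strains by calls therefore depends on the shared spread.

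In P18A, 13 genes changed, 9 higher and 4 lower. TRP1, the tryptophan synthesis gene also used as a selection marker, was at least 15.9-fold higher, since the reference was not well above background (log2 3.99 ± 0.21, SE, n = 2, limma adjusted p = 0.000437). YDR008C, a dubious reading frame that overlaps TRP1, was at least 3.39-fold higher on the same ground (1.78 ± 0.09), and URA3 rose 4.97-fold (2.31 ± 0.16). BNA2 and BNA1, enzymes that make NAD from tryptophan, rose 2.80-fold and 2.67-fold, YPR053C 2.23-fold, the subtelomeric COS12 2.22-fold, MET3, ATP sulfurylase, 1.67-fold and CPP3 1.64-fold. Besides NHP6A, MDH2 (log2 -1.43 ± 0.19), URA1 (-1.02 ± 0.12) and RPL7B (-0.74 ± 0.09) fell. At an unadjusted p under 0.05, 816 genes passed, where chance gives 292.

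Only RPL7B fell among the 138 ribosomal protein genes of P18A over all genes tested, while 46 fell adjusted over the list alone, and the list's median was -0.24 (camera adjusted p = 6.42e-16, adjusted p = 0.368 with an estimated correlation). By slide, the medians were -0.25 and -0.30. The 29 seripauperin and anaerobic mannoprotein genes include many near-identical seripauperin genes near chromosome ends, and their median was 0.31. Of the 29, limma called 0, and 9 were higher at an unadjusted p under 0.05 (camera adjusted p = 5.63e-07, adjusted p = 0.793 with an estimated correlation). On slides 1 and 2 the median was 0.29 and 0.31. Among the 33 Gcn4 targets limma called 0 over all genes and 5 higher adjusted over the list alone (13 higher and 1 lower at an unadjusted p under 0.05), with a median of 0.24 (camera adjusted p = 2.13e-06, adjusted p = 0.558 with an estimated correlation). The median was 0.21 on slide 1 and 0.25 on slide 2. COS12 was the 1 member of the 12 COS genes that rose, with 7 adjusted over the list alone and a median of 0.34 (camera adjusted p = 4.52e-06, adjusted p = 0.542 with an estimated correlation). Slide 1 gave a median of 0.23 and slide 2 one of 0.34. The 10 histone genes had a median of -0.31 with 0 called by limma and 6 lower both adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.000219, adjusted p = 0.368 with an estimated correlation). By slide, the medians were -0.33 and -0.26. In the general stress list limma called 0 of 38 genes in P18A, also adjusted over the list alone, and 9 were higher and 2 lower at an unadjusted p under 0.05 (median 0.36, camera adjusted p = 0.000222, adjusted p = 0.793 with an estimated correlation). On slides 1 and 2 the median was 0.29 and 0.45. In P18A 8 genes passed with the slide as a block, and the count was 4 without replicate 1, 2 without replicate 2, 27 from the deposited log ratios, 5 with median centring, 3 with a trended robust spread, 339 with only the P18A arrays in the fit and 2 with the outlier spots left in the background fit. Leaving out 1 deletion array gave 6 and 1 F48A array gave 8.

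In F48A, 496 genes changed, 287 higher and 209 lower, and 75 by at least 2-fold. TRP1 was at least 32.5-fold higher (log2 5.02 ± 0.21, SE, n = 2, limma adjusted p = 0.000163), SMK1, a MAP kinase gene of spore wall formation that lies beside YPR053C, rose 9.22-fold (3.21 ± 0.29) and URA3 8.43-fold (3.08 ± 0.16). ARG1 and ARG4, of arginine synthesis, rose 3.12-fold and 2.98-fold, GCV1 3.09-fold, HPF1 2.97-fold, BNA1 2.78-fold and YLR112W 2.72-fold. The largest decreases were in HXT1 (-2.83 ± 0.34), PHO84 (-2.74 ± 0.21), MF(ALPHA)2 (-2.69 ± 0.42), MDH2 (-2.67 ± 0.19), RPL8A (-2.19), NMD5 (-2.06), PHO89 (-2.03) and URA1 (-2.00). URA4, dihydroorotase of pyrimidine synthesis (-1.61), and SAM2, S-adenosylmethionine synthetase (-1.54), fell too.

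Of the 33 Gcn4 targets in F48A, 15 rose and 0 fell (23 rose adjusted over the list alone), with a median of 0.49 (camera adjusted p = 2.18e-09, adjusted p = 0.542 with an estimated correlation). The median was 0.45 on slide 1 and 0.42 on slide 2. Of the 14 phosphate genes 8 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.49 (camera adjusted p = 1.20e-08, adjusted p = 0.368 with an estimated correlation). Slide 1 gave a median of -0.56 and slide 2 one of -0.62. Ribosomal protein genes fell in 21 of 138 cases and rose in 0 (38 adjusted over the list alone; median -0.26, camera adjusted p = 1.89e-10, adjusted p = 0.423 with an estimated correlation). By slide, the medians were -0.24 and -0.29. Of the 29 seripauperin and mannoprotein genes 11 rose, PAU20 by 0.79 the most, and 22 rose and 1 fell adjusted over the list alone (median 0.52, camera adjusted p = 7.03e-07, adjusted p = 0.793 with an estimated correlation). On slides 1 and 2 the median was 0.81 and 0.21. CUP1-1 and CUP1-2 rose by 1.34 and 1.32, LYS2 by 0.71, and MET17, of methionine synthesis, fell (-1.37). The general stress list was not called (median 0.29, limma camera adjusted p = 0.0843), its median being -0.24 on slide 1 and 0.71 on slide 2. Within it HSP12 rose by 1.09, and HSP26, a small heat shock protein, fell (-0.86).

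Smaller groups in F48A gave 4 of 12 purine genes higher, GCV1 and GCV3 (by 1.28) among them, with 6 adjusted over the list alone (median 0.38, camera adjusted p = 0.00443, adjusted p = 0.439 with an estimated correlation). The median was 0.54 on slide 1 and 0.25 on slide 2. Of 19 pheromone response genes 3 rose, PRM10 by 0.58 among them, and 4 adjusted over the list alone (median 0.29, camera adjusted p = 0.00569, adjusted p = 0.793 with an estimated correlation). Slide 1 gave a median of 0.41 and slide 2 one of 0.23. In P18A the list was called in the other direction, with a median of -0.25 (limma camera adjusted p = 0.00458, adjusted p = 0.793 with an estimated correlation), -0.36 on slide 1 and -0.14 on slide 2, where limma called 0 members, also adjusted over the list alone, and 7 were lower and 1 higher at an unadjusted p under 0.05. Of 18 sulfur assimilation genes 4 fell, SAM2 the most and MET2 (-0.68), and 8 fell and 2 rose adjusted over the list alone (median -0.23, camera adjusted p = 0.0441, not called with the slide as a block, adjusted p = 0.558 with an estimated correlation). By slide, the medians were -0.29 and -0.09. This list too was called the other way in P18A, with a median of 0.17, 1 member higher and 3 adjusted over the list alone (limma camera adjusted p = 0.0183, adjusted p = 0.554 with an estimated correlation), and medians of 0.25 and 0.11 by slide. In F48A 378 genes passed with the slide as a block, and the count was 44 without replicate 1, 90 without replicate 2, 183 with either P18A array left out, 294 with either deletion array left out, 288 with a trended robust spread, 73 with median centring, 28 with the outlier spots left in the background fit and 3 with only the F48A arrays in the fit.

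In M29A, 211 genes changed, 93 higher and 118 lower, and 28 by at least 2-fold. TRP1 was at least 35.1-fold higher (log2 5.13 ± 0.21, SE, n = 2, limma adjusted p = 0.000138), URA3 rose 7.97-fold (2.99 ± 0.16), SMK1 4.48-fold (2.16 ± 0.29) and PIC2, a mitochondrial phosphate and copper carrier, 3.30-fold (1.72 ± 0.29). AIM33 rose 2.35-fold, YLR112W 2.32-fold, CUP1-1 2.24-fold, BNA1 2.21-fold and the peroxin gene PEX21 2.21-fold. The lipid droplet gene PLN1 rose as well (log2 1.14 ± 0.15). The largest decreases were in MDH2 (-2.65 ± 0.19), HXT1 (-2.05 ± 0.34), URA1 (-2.03 ± 0.12), NMD5 (-1.77), CWP1 (-1.55), RIB4, of riboflavin synthesis (-1.47), URA4 (-1.47), PHO89 (-1.38), RPL8A (-1.34) and MET17 (-1.21). HMO1 fell as well (-0.66).

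Ribosomal protein genes fell in 15 of 138 cases and rose in 0 in M29A (47 fell adjusted over the list alone), with a median of -0.32 (camera adjusted p = 2.05e-19, adjusted p = 0.368 with an estimated correlation). On slides 1 and 2 the median was -0.32 and -0.33. Of the 14 phosphate genes PHO84 (-1.13) and PHO89 (-1.38) fell, and 10 fell adjusted over the list alone (median -0.38, camera adjusted p = 1.55e-05, adjusted p = 0.417 with an estimated correlation). The median was -0.37 on slide 1 and -0.43 on slide 2. Of 33 Gcn4 targets 4 rose, ARG4 by 0.88 the most, and LYS20 fell, at -0.96 (10 higher and 2 lower adjusted over the list alone; median 0.24, camera adjusted p = 0.000729, adjusted p = 0.723 with an estimated correlation). Slide 1 gave a median of 0.14 and slide 2 one of 0.37. Respiratory chain and ATP synthase genes had a median of -0.25 with 1 of 35 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.0111, lost with median centring at adjusted p = 0.0545, adjusted p = 0.804 with an estimated correlation), but this was -0.50 on slide 1 and 0.06 on slide 2. In the 21 G1/S genes limma called 0 over all genes and 5 lower adjusted over the list alone (10 lower at an unadjusted p under 0.05; median -0.30, -0.65 on slide 1 and -0.05 on slide 2; camera adjusted p = 8.46e-05, adjusted p = 0.793 with an estimated correlation). The general stress list had a median of 0.13 and was not called (limma camera adjusted p = 0.564). In M29A 87 genes passed with the slide as a block, and the count was 7 without replicate 1, 13 with either P18A array left out, 14 with either deletion array left out, 7 with median centring, 4 with a trended robust spread and 1 with the outlier spots left in the background fit. With only the M29A arrays in the fit limma called 0 genes, with 813 at an unadjusted p under 0.05.

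**Figure D3:**
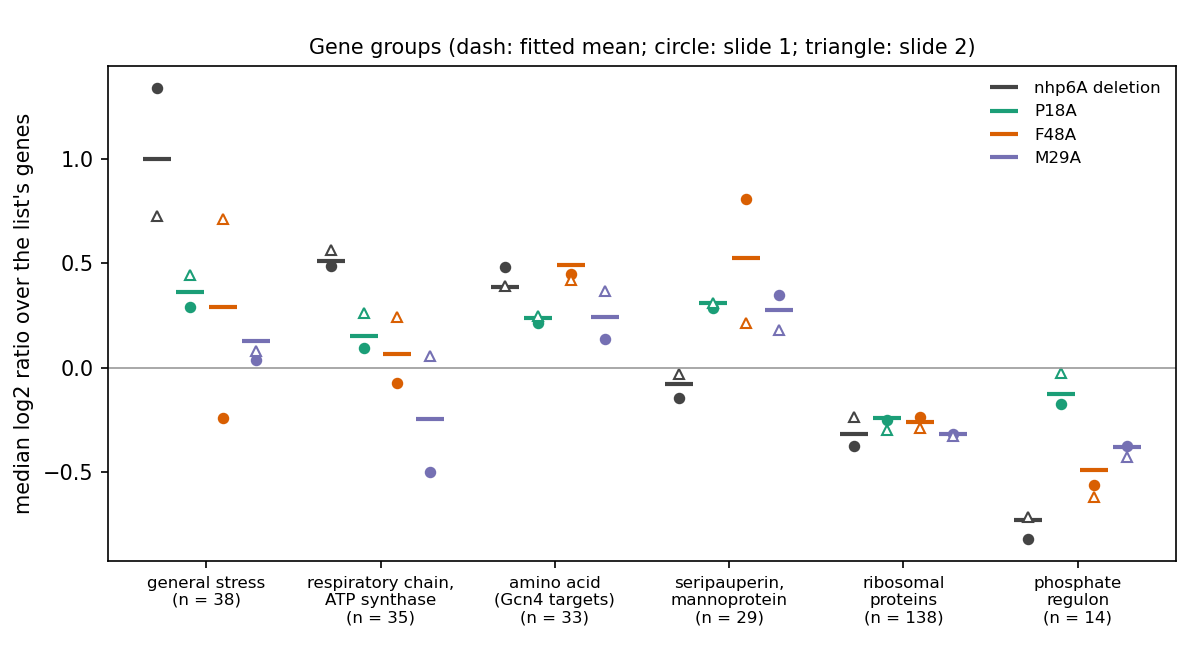
Median log2 ratio over the genes of 6 groups fixed beforehand, with a dash for the fitted mean of 2 arrays, a filled circle for the array on slide 1 and an open triangle for that on slide 2. Ribosomal protein medians lie between -0.37 and -0.23 on all 8 arrays, and the general stress median of F48A lies at -0.24 on slide 1 and 0.71 on slide 2.

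Over the 40 gene lists and 4 genotypes, camera called 56 of 160 tests at the preset correlation of 0.01, with 16 in the deletion, 18 in P18A, 11 in F48A and 11 in M29A. With a correlation estimated from the data, 0 of the 160 were called. The p-values rose also where the estimate lay below the preset 0.01. For the histone genes in P18A it was -0.038, and camera's unadjusted p went from 2.33e-05 to 0.0115. Losing the calls with this setting therefore does not show that correlation between genes accounts for them. The fry test called 30. It asks whether a list's genes move, on balance, one way, and compares no list with other genes. By limma's fry, the phosphate regulon was called in the deletion (adjusted p = 0.00341), F48A (adjusted p = 0.00483) and M29A (adjusted p = 0.0148), and ribosomal protein genes in all 4 genotypes (adjusted p between 0.0121 and 0.0176). The general stress list was not called by limma's fry in the deletion (adjusted p = 0.0632). With the slide as a block, camera called 51 of the 160 tests. Each slide held all 4 genotypes, so this block leaves the medians of the lists as they are.

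The P18A strain differed from the deletion in 77 genes, 19 higher and 58 lower in P18A. NHP6A was at least 13.5-fold and TRP1 at least 16.6-fold higher in P18A, as neither was well above background in the deletion. The phosphate transporter PHO84 was 5.80-fold higher (log2 difference 2.54 ± 0.29, SE, n = 2 arrays per genotype, limma adjusted p = 0.0162), the glucose transporter HXT4 4.33-fold and RPL8A 3.44-fold. The largest differences downwards in P18A were GRE1 at -2.79 ± 0.18, HSP26 at -2.54 ± 0.21, PIR3 at -2.43 ± 0.24, the peroxisomal citrate synthase CIT2 at -2.33 ± 0.37 and HPF1 at -2.32 ± 0.35. A block for the slide left 55 genes, and the count was 5 with either P18A array left out, 10 and 8 without deletion replicates 1 and 2, 131 with either M29A array left out, 41 with a trended robust spread, 23 with median centring, 2 with the outlier spots left in the background fit and 276 with only these 2 genotypes in the fit.

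F48A differed from the deletion in 15 genes, 3 higher and 12 lower. The 3 higher genes were NHP6A, at least 47.6-fold, TRP1, at least 34.0-fold, and SMK1, at least 11.6-fold (log2 difference 3.53 ± 0.41, SE, n = 2 arrays per genotype, limma adjusted p = 0.0226), none of them well above background in the deletion. HSP26 lay at -2.79 ± 0.21, PIR3 at -2.72 ± 0.24, GRE1 at -2.44 ± 0.18, the multidrug exporter QDR2 at -2.14 ± 0.16 and YBR116C at -2.14 ± 0.27. A block for the slide left 9 genes, and the count was between 6 and 7 without an array of F48A, P18A or the deletion, 28 from the deposited log ratios, 27 from Agilent's processed signals, 7 with median centring, 8 with only these 2 genotypes and 1 with the outlier spots left in the background fit.

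M29A differed from the deletion in 20 genes, 2 higher and 18 lower. NHP6A was at least 52.6-fold and TRP1 at least 36.7-fold higher in M29A, neither of them well above background in the deletion. PIR3 lay at -2.81 ± 0.24 (SE, n = 2 arrays per genotype, limma adjusted p = 0.00506), HSP26 at -2.66 ± 0.21, GRE1 at -2.43 ± 0.18, YBR116C at -2.30 ± 0.27 and HSP12 at -2.26 ± 0.30. SMK1, not well above background in the deletion, did not pass (limma adjusted p = 0.0670). A block for the slide left 7 genes, and the count was 8 and 119 without M29A replicates 1 and 2, 4 and 8 without deletion replicates 1 and 2, 9 with either P18A array left out, 8 with median centring, 5 with only these 2 genotypes and 1 with the outlier spots left in the background fit.

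Among the substitution strains few differences passed. F48A and P18A differed in 2 genes, the putative RNA-binding protein gene MIP6 at -1.47 ± 0.15 and YDR008C at -1.23 ± 0.12 (SE, n = 2 arrays per genotype, limma adjusted p = 0.0448 for both). MIP6 read 0.56 ± 0.10 in P18A against the reference, which did not pass, and fell in F48A (-0.91). At an unadjusted p under 0.05, 669 genes passed. Between M29A and P18A limma called 0 genes, with 394 at an unadjusted p under 0.05, and between F48A and M29A 0 genes, with 84 where chance gives 292. Under the shared spread, a typical gene's 95% interval reached 0.40 on the log2 scale either side of these differences. With fewer genes than chance gives, that interval need not hold between F48A and M29A. Across genes, M29A replicate 2 correlated at 0.708 and 0.841 with F48A replicates 1 and 2, and at 0.373 with the other M29A array. The 0 calls therefore do not show that these 2 strains are alike. The 2 calls between F48A and P18A were lost with the slide as a block and when 1 array of the deletion, P18A or F48A was left out, and with either M29A array left out 15 genes differed. Without M29A replicate 2, 19 genes differed between M29A and P18A and 72 between F48A and M29A, and without replicate 1 the count was 1 between M29A and P18A.

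A moderated F test over the 4 genotypes called 20 genes. Besides NHP6A and TRP1 these include the stress and cell wall genes GRE1, HSP26, PIR3 and SSA3, the phosphate transporter PHO84, the multidrug exporter QDR2 and SMK1. PHO84 lay at -2.92 in the deletion, -0.38 in P18A, -2.74 in F48A and -1.13 in M29A, with an SE of 0.21 (limma adjusted p = 0.0344). SMK1 was not well above background in the deletion and lay at -0.22 in P18A, 3.21 in F48A and 2.16 in M29A, with an SE of 0.29 (limma adjusted p = 0.0344). In opposite directions in different genotypes, 3 genes passed: HSP26 at 1.93 in the deletion against -0.86 in F48A and -0.74 in M29A, QDR2 at 0.83 against -1.31 and -0.95, and YET3, an endoplasmic reticulum protein gene, at 0.82 in the deletion against -0.65 in M29A. YET3 lies outside the naming rule and is named because the set holds only 3 genes. With the slide as a block 7 genes passed the F test, and the count was 1 and 2 without deletion replicates 1 and 2, 4 with either P18A array left out, 9 and 8 without F48A replicates 1 and 2, and 94 without M29A replicate 2.

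Against the reference 6 genes passed in all 4 genotypes. URA3, BNA1 and CPP3 rose in each, and URA1, MDH2 and RPL7B fell in each. BNA1 rose by 1.74, 1.42, 1.47 and 1.15 in the deletion, P18A, F48A and M29A. MDH2 lay at -2.57, -1.43, -2.67 and -2.65, and RPL7B at -1.22, -0.74, -1.13 and -0.89. In the deletion, F48A and M29A together, whatever the call in P18A, 72 genes rose and 85 fell.

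The size of each substitution's effect was set against that of the deletion across genes, using arrays of different slides so that the slide was not shared. A reference sample used on both slides would still be shared, and a dye effect of a gene common to all arrays would stay in the measure. Either would enter the values below. The relative effect size, 1 for an effect as large as the deletion's, was 0.281 for P18A, 0.711 for F48A and 0.415 for M29A. F48A replicate 2 correlated across genes with deletion replicate 1, on the other slide, at 0.779, and with the other F48A array at 0.511, so variation that is not of the genotype may add to the value of F48A. The 2 pairings of slides gave 0.341 and 0.222 for P18A, 0.799 and 0.622 for F48A, and 0.477 and 0.354 for M29A. Over the 1434 genes called in the deletion it was 0.273, 0.602 and 0.427. Median centring gave 0.169 for P18A, and leaving the outlier spots in the background fit gave 0.633, 1.72 and 0.999 for P18A, F48A and M29A.

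**Figure D4:**
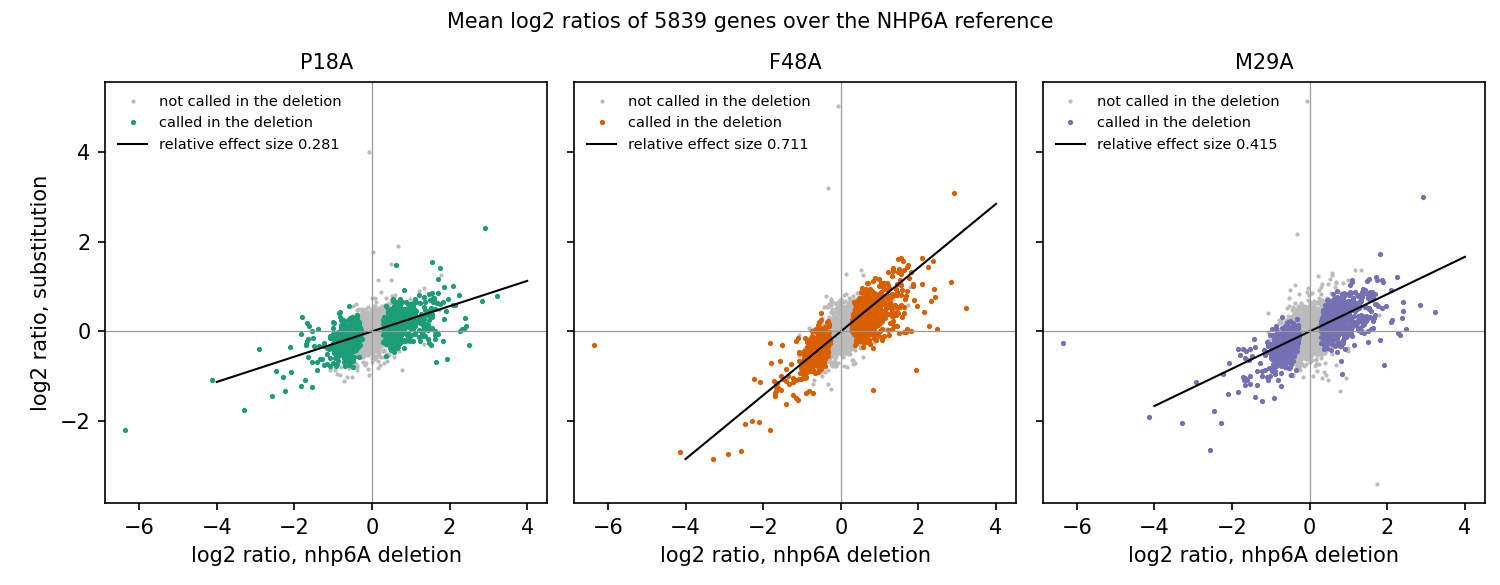
Mean log2 ratio over the NHP6A reference in each substitution strain against that in the deletion for 5839 genes, coloured where the gene passed in the deletion. The line has the slope of the relative effect size, 0.281 for P18A, 0.711 for F48A and 0.415 for M29A.

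The deletion and F48A shared 227 higher and 175 lower genes, where independent lists of these sizes would share 41.2 and 21.3. F48A and M29A shared 82 and 100 (4.57 and 4.22 for independent lists), and the deletion and M29A 77 and 89 (13.35 and 12.04 for independent lists). These expected numbers do not allow for the reference that all genotypes share. The mean log2 ratios correlated across genes at 0.796 for F48A and M29A, 0.715 for the deletion and F48A, 0.547 for the deletion and M29A, 0.519 for the deletion and P18A, 0.514 for P18A and M29A, and 0.497 for P18A and F48A. Simulated unchanged genotypes against a reference shared by the arrays of a slide gave 0.505, so part of these values may come from the shared reference. Arrays of a slide deviated from their group means with correlations from -0.56 to 0.34, so the data do not show the sharing by slide that the simulation assumes. The covariance of the means was 0.113 for the deletion and F48A, 0.0859 for F48A and M29A, 0.0764 for the deletion and M29A, 0.0575 for the deletion and P18A, 0.0426 for P18A and F48A, and 0.0389 for P18A and M29A, against 0.0152 in the simulation. Between arrays of different slides it was 0.130 for the deletion and F48A (0.0964 within slides), 0.0758 for the deletion and M29A, 0.0749 for F48A and M29A, 0.0514 for the deletion and P18A, 0.0420 for P18A and F48A, and 0.0401 for P18A and M29A.

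Chromosomes and arms were tested as 48 lists. The right arm of chromosome IX was called higher by camera in all 4 genotypes, with medians over its 43 genes of 0.23 in the deletion, 0.17 in P18A, 0.19 in F48A and 0.21 in M29A (camera adjusted p between 0.0129 and 0.0136, adjusted p = 0.623 with an estimated correlation). Its medians were 0.26, 0.09, 0.12 and 0.14 on slide 1 and 0.26, 0.18, 0.21 and 0.22 on slide 2, and the 4 calls held with the slide as a block and were lost with median centring. In the deletion 16 of its genes rose, among them DAL7, of allantoin breakdown (by 0.80), and 3 fell. Array medians over all chromosome arms lay between -0.15 and 0.26, where a whole extra copy in a haploid strain would give 1.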

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

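The tests of differences between genotypes were planned, those of uneven spots and of an intensity bias were fixed before their results were seen, and the other tests of explanations were chosen only after the result was seen.

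URA3 rose in all 4 genotypes while URA1 and URA4 lay below 0, and each of these belongs to pyrimidine synthesis. A loss of Nhp6A activity in proportion to each genotype's effect on other genes is excluded as the only cause for URA3. Its P18A value of 2.31 lay 9.06 standard errors from the 0.82 so predicted. Such a loss is left open for URA1 and URA4, at 3.75 standard errors (-0.85 against -0.52). A dye effect as the only cause is excluded for URA1 and URA4. It would be alike on all arrays, and their mean differed between P18A and F48A by 7.96 standard errors (-0.85 and -1.81). URA3 was not tested for a dye effect, and a dye part beside an effect of the genotype is left open. A URA3 marker that differs between the reference and the other strains remains a candidate explanation, as the labels name no marker. The genes beside URA3, GEA2 and TIM9, stayed within 0.484 on the log2 scale. They would stay so under any cause that changes URA3 alone, so they do not favour a marker.

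NHP6A was low in P18A. Of YPR053C and SMK1, which lie beside it, YPR053C was high in all substitution strains, and SMK1 in F48A and M29A but not in P18A. Faulty spots are excluded, as the 14 NHP6A spots of the P18A arrays ranged over only 0.233. The values argue against a loss of Nhp6A activity that raises SMK1. That gene was not well above background in the deletion and rose in F48A and M29A (3.21 and 2.16). Its smaller fitted difference from the deletion, in M29A, was 6.02 standard errors and did not pass (limma adjusted p = 0.0670). The deletion also alters the locus near SMK1, so this strain does not exclude such a loss. A TRP1 marker placed beside NHP6A in the substitution strains remains a candidate. TRP1 was high there, while SOK1 and GAL3, beside TRP1, MAK3, on the other side of NHP6A, and SEC8, beyond SMK1, stayed within 0.341. SMK1 lay at -0.22 in P18A, however. YDR008C, which overlaps TRP1, lay at 1.78 in P18A against 0.54 in F48A and 0.61 in M29A. The values therefore do not show a placement common to all of these strains. Weaker binding of the probe to the P18A transcript, which would lower NHP6A there alone (-1.91 against the mean of F48A and M29A), could not be told apart without the probe sequence.

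Ribosomal protein genes had medians between -0.37 and -0.23 on all 8 arrays. Spot intensity alone does not account for these medians in the normalized ratios. Of 10000 random lists of other genes matched on intensity, 0 reached so low a median in any genotype. Loess had centred the ratios by intensity beforehand, so such lists lie near 0 by construction. The lists drew from as few as 29 genes of like intensity and so overlapped, and their count is no measure of chance. The values argue against scaling alone with each genotype's effect on other genes. The P18A median was at least 0.673 of the deletion's, against a relative effect size of 0.281 (0.341 and 0.222 by pairing of slides). A dye effect of these genes could give such a like shift, with a range of 0.139 over the arrays. Without a dye swap it is left open, and added to a scaled change it would raise that ratio too. A scaled part is therefore not excluded.

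Differences between groups were found in these genes, where NHP6A, TRP1 and SMK1 were not well above background in the deletion, so that their fitted values do not measure the size of a difference from it. Between P18A and the deletion they were NHP6A (4.17), TRP1 (4.06), PHO84 (2.54), HXT4 (2.11), RPL8A (1.78), GRE1 (-2.79), HSP26 (-2.54), PIR3 (-2.43), CIT2 (-2.33) and HPF1 (-2.32). Between F48A and the deletion they were NHP6A (6.06), TRP1 (5.09), SMK1 (3.53), HSP26 (-2.79), PIR3 (-2.72), GRE1 (-2.44), QDR2 (-2.14) and YBR116C (-2.14). Between M29A and the deletion they were NHP6A (6.11), TRP1 (5.20), PIR3 (-2.81), HSP26 (-2.66), GRE1 (-2.43), YBR116C (-2.30), HSP12 (-2.26) and YET3 (-1.47), which passed in opposite directions in these strains. Between F48A and P18A they were MIP6 (-1.47) and YDR008C (-1.23). Of the spike-in control spots, on which the series does not report, 100% stood well above background in both channels on all arrays.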

How the results depend on the processing

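Apart from the alternatives fixed in advance, the tests with the outlier spots left in the background fit and with crossed replicate numbers were chosen only after the result was seen. Over 21 alternatives the named genes kept 3919 of 5119 calls and lost 1200 (23.4%). Another 173 calls were gained, and 0 calls were reversed. Scaling between arrays, counted among these alternatives, leaves the log2 ratios as they are and so could change no call. The blocks, the trended spread, the filters and the fit of only the arrays compared leave the fitted ratios as they are. They could therefore reverse no call. Nor could leaving out an array, as each call had its arrays on the same side. Only the other ways of computing the ratios could have reversed a call. Counts of genes and of lists carry no sign, so they could not reverse in this way. The order of P18A and F48A by calls did change. It went from 13 and 496 to 339 and 3 with only a genotype's own arrays in the fit. Array medians stayed within 0.05 of 0 in each of the 8 ways of computing the ratios. Loess and median centring set them near 0 by construction, so this does not test the ratios made with them. With 87.2% to 93.2% of spots well above background, most changes of the dimmest genes are given as bounds or not tested. Stricter thresholds give fewer calls by construction. For the other alternatives, filters and left-out arrays included, the cause of a change in a count was not tested.

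Median centring without loess gave 441 genes in the deletion, with 75.7% of them higher against 58.4%, 5 in P18A, 73 in F48A and 7 in M29A. It gave 23, 7 and 8 genes between P18A, F48A or M29A and the deletion, 0 between F48A and P18A, 5 in the F test, 132 named genes, relative effect sizes of 0.169 for P18A and 0.303 for M29A, and 0 chromosome lists. With the outlier spots left in the background fit, the counts were 41 in the deletion, 2 in P18A, 28 in F48A and 1 in M29A, then 2, 1 and 1 against the deletion, 0 between F48A and P18A, 2 in the F test and 29 named genes, with relative effect sizes of 0.633, 1.72 and 0.999. Agilent's processed signals gave 25 genes in P18A and 27 between F48A and the deletion. The deposited log ratios gave 27 in P18A, 28 between F48A and the deletion, 9 between F48A and P18A and 6 between M29A and P18A. A trended robust spread gave 3 in P18A, 288 in F48A, 4 in M29A, 41 between P18A and the deletion, 0 between F48A and P18A and 6 in the F test. With only the arrays compared, the counts were 339 in P18A, 3 in F48A, 0 in M29A, then 276, 8 and 5 against the deletion and 6 between F48A and P18A.

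Between F48A and P18A the median of the spots gave 10 genes, no filter 0 and the strict filter 0, which also gave 34 in the F test. No background correction gave 1 gene between M29A and P18A. At 2-fold and above, 180, 75 and 28 genes remained in the deletion, F48A and M29A. At an adjusted p under 0.01, 442, 6, 75 and 10 remained in the deletion, P18A, F48A and M29A, then 7, 7 and 7 against the deletion, 0 between F48A and P18A and 7 in the F test. An estimated correlation gave 0 gene lists and 0 chromosome lists. Of the 56 gene list calls, median centring lost 10 and gained 11, Agilent's processed signals lost 6 and gained 4, no background correction lost 3 and gained 1, and the fixed block lost 6 and gained 1.

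The replicate number marks the slide. Arrays of a slide deviated from their group means with correlations from -0.56 to 0.34, so the numbers do not pair the arrays. The replicate block as a fixed term gave 1348, 8, 378 and 87 genes in the deletion, P18A, F48A and M29A, then 55, 9 and 7 against the deletion, 0 between F48A and P18A, 7 in the F test, 217 named genes, 51 gene lists and 4 chromosome lists. As a random block it gave 0 between F48A and P18A and moved no other count by over 1.5 times. Crossing the numbers of F48A gave 12 genes between F48A and the deletion, against 9 with the block and 15 without.

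Leaving out 1 array at a time, the lone array being assumed to vary like the others, gave 165 to 1528 genes in the deletion, 2 to 12 in P18A, 44 to 661 in F48A and 7 to 187 in M29A. It gave 5 to 131, 6 to 20 and 4 to 119 between P18A, F48A or M29A and the deletion. The other ranges were 0 to 15 between F48A and P18A, 0 to 19 between M29A and P18A, 0 to 72 between F48A and M29A, 1 to 94 in the F test and 115 to 258 named genes. The highest of these for M29A against the deletion, F48A against M29A and the F test came without M29A replicate 2.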

Other observations

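The hypothesis about chromosome ends was tested with a list chosen only after the data were seen, and its prediction was written before the tests were run.

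Further gene groups moved in the deletion. Of 16 genes under nitrogen catabolite repression 8 rose, PUT4, the proline permease (0.90), and DAL7, of allantoin breakdown (0.80), the most, while the ammonium permeases MEP1 (-1.55) and MEP3 (-1.08) fell (median 0.39, limma camera adjusted p = 0.0294, lost with median centring at adjusted p = 0.145, adjusted p = 0.558 with an estimated correlation). The same 8 and 2 passed adjusted over the list alone, and the medians were 0.31 and 0.51 on slides 1 and 2. Of 20 iron regulon genes 4 fell, among them the siderophore transporter SIT1 (-1.72) and the ferric reductase FRE4 (-1.55), and the heme oxygenase HMX1 rose (0.98). The list had a median of -0.36 (limma camera adjusted p = 0.0166, adjusted p = 0.804 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone, and -0.19 and -0.36 on slides 1 and 2. The high-affinity copper transporter CTR1 (-1.01) and zinc transporter ZRT1 (-1.42) fell too.

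Lipid genes went both ways in the deletion. Of 11 phospholipid and inositol genes 6 fell and 0 rose, CHO2, of phosphatidylcholine synthesis (-1.35), and FAS1, fatty acid synthase (-0.86), the most (median -0.37, limma camera adjusted p = 0.0414, adjusted p = 0.558 with an estimated correlation). The same 6 fell adjusted over the list alone, the medians were -0.30 and -0.44 on slides 1 and 2, and the camera call was lost with the slide as a block and from Agilent's processed signals. Of 25 ergosterol genes 5 rose and 3 fell, with ERG2 (0.95) and ERG9 (0.83) highest and HMG2 (-0.92) and ERG6 (-0.70) lowest (limma camera adjusted p = 0.177). Of 12 COS genes 7 rose, COS3 (0.75) and COS2 (0.74) the most, and COS8 fell (-0.58), with the same counts adjusted over the list alone. The list's median was 0.46 (limma camera adjusted p = 0.0471, adjusted p = 0.793 with an estimated correlation, lost with the slide as a block, with median centring, from Agilent's processed signals and with no background correction), and 0.41 and 0.42 on slides 1 and 2.

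The COS genes lie near chromosome ends, and the hypothesis was that loss of Nhp6A raises genes there. For the 10 outermost measured genes of each end, 320 in all, the deletion median was 0.0178, with 47 genes higher and 36 lower, and limma's camera did not call the list (adjusted p = 0.714), so the hypothesis did not hold. In P18A the median was 0.0980, with 1 gene higher and 1 lower, and camera called the list (limma camera adjusted p = 6.29e-05, adjusted p = 0.217 with an estimated correlation). The P18A median was 0.0765 over the 285 genes outside the COS, seripauperin and flocculin lists. In F48A and M29A the list of 320 was not called (limma camera adjusted p = 0.110 and 0.156).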
